A study of Mus musculus with 16 samples.

How the data were processed

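Retinal microglia of wild-type C57BL/6 mice were compared at 4 ages, 3, 12, 18 and 24 months, with 4 arrays per age and 16 arrays in all. Per the labels, the cells were sorted by flow cytometry on CD11b, a surface integrin of microglia that monocytes, macrophages, neutrophils, natural killer cells and some dendritic cells also carry. The labels call the arrays of an age biological replicates, and they do not say whether a replicate is 1 animal or a pool. Per the labels, less than 5 ng of total RNA was amplified, biotinylated and hybridised to Affymetrix Mouse Exon 1.0 ST arrays, which carry probes along the exons of each transcript.

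The deposited values are log2 expression levels made with RMA, per the submitters' processing notes. RMA subtracts background, equalises the distributions of the arrays at probe level and summarises the probes of a feature. Its version, the probe sets used and any filter are not given in the sources used here. The table held 16755 features on each of the 16 arrays, and every column of values was used (0 left out). Array medians ran from 6.88 to 7.18 and the values from 4.48 to 14.34, so the features' distributions were not fully equal between arrays. Low starting amounts and amplification can add spread between arrays, and values near the lower end are compressed towards a common floor. The number of arrays limits the precision.

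Gene symbols came from the array's annotation table. Of the features, 14996 had 1 symbol, 1019 had several and 740 had none, and only features with 1 symbol were named. Symbols were checked through Entrez identifiers against a gene table of assembly GRCm38.p6, which was used for names only. Of the features with 1 symbol 14941 matched and 0 symbols differed. A further 135 symbols were carried by more than 1 feature. Feature numbers are given as deposited, and no coordinates were used.

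Each feature was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust) with 1 mean per age over all 16 arrays, so that the ages shared 1 estimate of the spread. The comparisons were 12, 18 and 24 months against 3 months, 18 against 12 months and 24 against 18 months. A moderated F test asked whether the 4 ages differed, and a linear model in months asked for a linear trend. P-values were adjusted by the Benjamini-Hochberg method over all 16755 features, with a threshold of 0.05 and no fold threshold. No feature was filtered out. The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

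The 38 gene lists, 22 of biology and 16 of cell type markers, were tested with camera in limma at its preset correlation of 0.01 between genes, with 1 feature per gene (the one with the highest mean), and adjusted over the lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. A list's score on an array is the mean of its members after centring each on its mean over the 16 arrays. Scores were compared between ages by an exact two-sided permutation test, whose smallest p for 4 against 4 arrays is 0.0286. Counts of members are given from the adjustment over all features and, where stated, adjusted over the list alone.

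Genes were named by rule. Among features with 1 symbol past the threshold and with no overlap between the groups, these were the 10 with the largest rise and the 10 with the largest fall. Where fewer than 5 passed, the 5 smallest p-values in each direction were named as not passing. For the trend these were the 5 smallest p-values in each direction. Lists contributed up to 4 members with the smallest p, cell type lists their brightest member and the one with the smallest p at 24 months, and 7 genes served as an identity check of the sort. Tctex1d4 and Bag2 fall outside this rule and were chosen after their values were seen.

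The alternatives fixed beforehand were leaving out the dimmest features (a share of 0.333 by mean level), quantile normalization, median centring, a trended and robust variance, array weights, fitting only the ages compared, 1 feature per gene, other thresholds, log2 of age, other set tests, leaving out each array in turn, and 3 terms for structure between arrays. These were the replicate number as a block, the array numbers in groups (1 to 8 or 9 to 16) as a block, and the array number as a covariate. The array number is a running number that the labels give each array without saying what it means. After seeing the data, 7 alternatives were added: the rod score, the homeostatic microglia score or both as covariates, leaving out the 3 arrays lowest in microglia genes, the 2 lowest in rod genes or all 5, and averaging 18-month replicates 1 and 2.

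The fits were tested on simulated data with the spread of the real features, each feature drawn independently of the others. For 24 against 3 months, with 50 features changed at each size among 16755, changes of 0.5, 1, 2 and 4 on the log2 scale were recovered in 20%, 52%, 86% and 100% of features, with 10 false calls. The trend fit recovered 183 of 200 features changed by 0.1 per month, with 5 false calls. For 24 against 3 months, camera called a planted lysosome list and 0 of the other lists. The false calls and the camera result thus do not cover genes that move together, as many did on the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.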

Results

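Gene expression was measured in microglia sorted on CD11b from the retinas of mice aged 3, 12, 18 and 24 months, to ask how retinal microglia change with age. Each age had 4 biological replicates on 4 exon arrays, and levels are log2 values. Array medians were 7.04 to 7.13 at 3 months, 7.04 to 7.18 at 12 months, 6.88 to 7.00 at 18 months and 6.92 to 6.98 at 24 months. The median feature differed by −0.04, −0.21 and −0.17 from 3 months at 12, 18 and 24 months, and a change relative to that median, given beside some list means and many of the falls, is the fitted one minus this difference. Since the labels do not say from how many animals a replicate came, p-values measure the spread between these samples.

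The fractalkine receptor gene Cx3cr1 (feature 6999456) stood at 12.55 ± 0.34 (SD, n = 4) at 3 months, 12.55 ± 0.35 at 12, 11.64 ± 1.14 at 18 and 11.97 ± 1.38 at 24 months. Aif1, which encodes the microglial marker Iba1, stood at 12.32 ± 0.47, 12.22 ± 0.35, 11.49 ± 0.96 and 11.90 ± 1.00. The CSF1 receptor gene Csf1r stood at 12.05 ± 0.21, 11.74 ± 0.50, 11.01 ± 1.17 and 11.44 ± 1.37. Itgam, which encodes the CD11b used for the sort, lay between 8.93 ± 1.29 at 18 months and 9.97 ± 0.99 at 3 months. For Ptprc, P2ry12 and Tmem119 the changes at 18 months were −1.01, −0.89 and −1.28, with standard errors of 0.629, 0.657 and 0.732. None of these 7 genes passed in limma in any comparison with 3 months; their smallest adjusted p was 0.194, for Tmem119 at 18 months. Without 18-month replicate 1 the changes at 18 months were −0.48 for Cx3cr1, −0.51 for Aif1, −0.59 for Csf1r, −0.63 for Itgam, −0.60 for Ptprc, −0.54 for P2ry12 and −0.85 for Tmem119, which was also −0.85 without 18-month replicate 2. With the rod and homeostatic microglia list scores as covariates, a fit chosen after the data were seen, they were −0.19, −0.0975, −0.32, 0.30, 0.0242, −0.0878 and −0.30. The microglia list holds Cx3cr1, Aif1, Csf1r, P2ry12 and Tmem119 itself, so their smaller changes in this fit are partly built in.

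Markers of other retinal cells were measured as well. Gnat1, the transducin alpha subunit of rods, stood at 11.19 ± 2.02 at 3 months and 13.32 ± 0.46 at 18 months (SD, n = 4), and Glul, the glutamine synthetase of Müller glia, at 12.99 ± 0.33 and 13.20 ± 0.15. The rod list score was lowest on 3-month replicates 3 (−2.11) and 4 (−2.53) and ran from −0.55 to 1.24 on the other 14 arrays. The homeostatic microglia score was lowest on 24-month replicate 1 (−1.77) and 18-month replicates 1 (−1.43) and 2 (−1.11), whose rod scores were 1.12, 1.00 and 1.24. On the remaining 13 arrays it ran from −0.45 to 0.64. The first principal component held 42.8% of the variance and placed these 3 arrays at 64.4 to 70.5 and 3-month replicates 3 and 4 at −53.1 and −52.6. The 18-month replicates 1 and 2 had a rank correlation across features of 0.990, against 0.824 to 0.973 for the other 119 pairs, and were kept as 2 arrays.

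**Figure D1:**
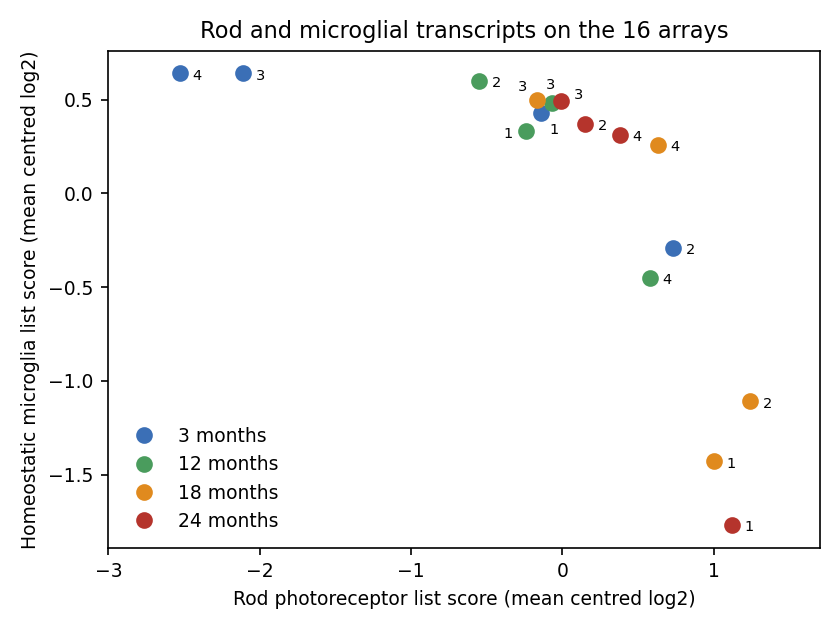
Homeostatic microglia list score against rod photoreceptor list score on each of the 16 arrays (both in log2 units, mean of centred members), coloured by age and marked with the replicate number. The 3 arrays lowest in microglia genes, 18-month replicates 1 and 2 and 24-month replicate 1, have rod scores of 1.00 to 1.24, and 3-month replicates 3 and 4 have rod scores of −2.11 and −2.53.

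At 12 months the largest evidence for single genes fell on Gnrh1, which encodes a releasing hormone, and Dimt1, an rRNA methyltransferase gene, and neither passed the threshold. Gnrh1 stood at 7.83 ± 0.40 against 6.15 ± 0.30 at 3 months (SD, n = 4; log2 change 1.68, SE 0.315, adjusted p = 0.450 in limma), and Dimt1 at 6.05 ± 0.31 against 7.59 ± 0.33 (−1.54, SE 0.254). The next were Armcx3 (1.07), Klhl18 (0.81), Rars2 (1.53) and Osbpl7 (0.63) on the higher side. On the lower side they were Fam243 (−0.72), Ccnq (−0.71), Saraf (−0.47) and the transketolase gene Tkt (−0.71). In limma 0 of 16755 features passed, 793 had an unadjusted p under 0.05 (237 higher, 556 lower), and 2.68% had groups without overlap, against 2.86% by chance.

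Markers of retinal cells other than microglia averaged higher at 12 months. The mean log2 change was 0.94 over 17 rod genes, 0.60 over 17 Müller glia and astrocyte genes, 0.53 over 12 cone genes and 0.50 over 15 endothelial genes. No member of these lists passed, and 0 passed adjusted over the list alone. Camera gave adjusted p of 9.25e-08, 1.9e-05, 0.0354 and 0.0354. For each of the 4 lists the adjusted p = 0.968 with an estimated correlation. The count of 4 lists was 2 without 3-month replicate 3, 2 without 3-month replicate 4, 2 without 12-month replicate 1 and 7 without 3-month replicate 2. Without 3-month replicates 2, 3 and 4 in turn, the rod mean was 1.52, 0.58 and 0.44, and the cone mean was 0.90, 0.25 and 0.27. The cone list no longer passed without 3-month replicates 3 or 4 or 12-month replicates 1 (0.46) or 4 (0.41). The endothelial list no longer passed without 3-month replicates 1 (0.48), 3 (0.35) or 4 (0.37) or 12-month replicates 1 (0.51) or 4 (0.11), and its mean was 0.80 without 3-month replicate 2 and 0.82 without 12-month replicate 2. The Müller mean was 0.36 without 3-month replicate 3 and 0.36 without 12-month replicate 4, where the list no longer passed. All 12-month arrays had array numbers 1 to 8, while 3-month replicates 3 and 4 had numbers 9 to 16. Within the numbers 1 to 8 the rod mean was −0.36 (4 arrays against 2) with 0 calls in limma, and with the number groups as a block it was 0.18. Without 3-month replicates 3 and 4 together, a fit chosen after the data were seen, the rod mean was −0.36 and the cone mean −0.26. With the rod score as a covariate, chosen likewise, the cone mean was −0.11 and the endothelial mean −0.0133, and with the microglia score added the cone mean was −0.0053. The Müller mean was 0.0159, 0.07 and 0.18 in these 3 fits, and neither the Müller nor the endothelial list passed in them.

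At 18 months 466 features rose and 3068 fell against 3 months. The largest rise was in Spa17 (feature 6994705), which encodes a protein of sperm and cilia: 9.65 ± 0.26 at 18 months against 5.62 ± 0.11 at 3 months (SD, n = 4), a log2 change of 4.03 (SE 0.499, adjusted p = 0.0101 in limma; 4.23 relative to the median feature). Its 3-month levels (5.49 to 5.75) lay below the mean of the dimmest features on those arrays (5.79 to 5.91), with no background measure used here, so no fold is given. Pla2g5, a secreted phospholipase gene, rose by 3.28 (SE 0.684), Stk39, a kinase gene of ion transport, by 3.11 (0.604), Etnppl, a phospholyase gene, by 3.11 (0.642), Ndrg2 by 3.08 (0.711), Enpp5 by 3.00 (0.737), Fam171b by 2.87 (0.841), Sox2, a transcription factor gene of glia and progenitors, by 2.79 (0.654), Pcolce2 by 2.73 (0.688) and Chic1 by 2.67 (0.732). The naming rule required all 4 arrays at 18 months to lie above all 4 at 3 months in these genes. Of all 16755 features 24.55% had groups without overlap, against 2.86% by chance for each feature alone. None of the 10 passed with both list scores as covariates, where the changes were 3.66 for Spa17, 2.55 for Pla2g5, 1.94 for Stk39, 2.25 for Etnppl, 1.73 for Ndrg2, 1.46 for Enpp5, 0.84 for Fam171b, 1.54 for Sox2, 1.73 for Pcolce2 and 2.33 for Chic1.

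Among the largest falls, the inflammasome receptor gene Naip2 fell by 1.85 (SE 0.618; −1.64 relative to the median feature), the histamine receptor gene Hrh2 by 1.61 (0.457; −1.40), Tnfsf13b, which encodes the B cell factor BAFF, by 1.60 (0.440; −1.39) and the leukocyte gene Lsp1 by 1.46 (0.489; −1.26). The bradykinin receptor gene Bdkrb1 (feature 6797744) fell from 6.95 ± 0.10 to 5.64 ± 0.32 (SD, n = 4), a change of −1.31 (SE 0.151, −1.10 relative to the median feature, adjusted p = 0.00889 in limma). The others among the 10 largest falls with no overlap between the groups were 1700094D03Rik (−1.73), Hspb3 (−1.54), Dennd1c (−1.51), Ly6m (−1.30, and −0.70 without 3-month replicate 2) and Olfr250 (−1.25). With both list scores as covariates Naip2 was −1.08, Hspb3 −0.93, Dennd1c −0.80 and Lsp1 −0.83, and of these 10 only Bdkrb1 passed. Of the 3068 falls, 1588 were among the dimmest features (a share of 0.333) and 56 exceeded 1 on the log2 scale, against 309 of the 466 rises. The median change was −0.46 among falls and 1.29 among rises.

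The count of 18-month calls moved with single arrays and with the scaling. In limma the count of 3534 became 0 without 3-month replicate 4, 10 without 3-month replicate 3, 1 without 18-month replicate 2, 3 without 18-month replicate 1 and 1253 without 3-month replicate 2. It was 12 without these dimmest features, and the share of falls was 54.0% of 100 calls after median centring and 63.2% of 38 after quantile normalization, against 86.8%. In fits chosen after the data were seen, the count in limma was 0 with the rod score as a covariate, 29 with the microglia score, 3 with both, 0 without the 3 arrays lowest in microglia genes, 10 without 3-month replicates 3 and 4, and 0 without these 5 arrays. With all arrays and no covariate 6979 features had an unadjusted p under 0.05.

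Of the 18-month genes named by rule, Spa17 and Bdkrb1 passed in the most alternatives, each without 14 of the 16 single arrays, followed by Etnppl and Pla2g5 (20 of 33) and Olfr250 (20 of 32). Spa17 passed in 26 of 33 alternatives, with changes of 3.59 to 4.18 and adjusted p of 5.01e-05 to 0.304 in limma. Bdkrb1 passed in 26 of 32, with changes of −1.53 to −1.01 and adjusted p of 2.59e-05 to 0.290. Both calls ended without 3-month replicate 4 (changes 3.98 and −1.28) and without 18-month replicate 2 (4.05 and −1.22). Within the array numbers 9 to 16, which held all 18-month arrays and 3-month replicates 3 and 4, 166 features rose and 50 fell, with changes of 4.11 for Spa17, −1.32 for Bdkrb1 and 2.99 for the rod list mean. The numbers 1 to 8 held no 18-month array, and with the number groups as a block, which gives more weight to 3-month replicates 3 and 4, the count was 3622.

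Genes of photoreceptors, bipolar cells and Müller glia made up part of the 18-month rises. In the Müller glia and astrocyte list 10 of 17 genes rose and 7 did not pass (11 rose and 1 fell adjusted over the list alone), among them the glutamate transporter gene Slc1a3 (2.16, SE 0.472), Sox2 and the clusterin gene Clu (2.28, SE 0.734). In the rod list 4 of 17 rose (14 adjusted over the list alone), with Gnat1 at 2.14 (SE 0.706; 1.38 without 3-month replicate 4, where it no longer passed) and the rhodopsin kinase gene Grk1 at 2.02 (0.662). Of 12 cone genes 1 rose (0 adjusted over the list alone), the opsin gene Opn1mw (1.60). Of 13 bipolar genes 2 rose, among them Otx2 (2.85), and 1 fell (4 and 1 adjusted over the list alone). The list means were 1.69 for rods, 1.39 for Müller glia, 1.08 for bipolar cells and 1.02 for cones, or 1.90, 1.59, 1.29 and 1.22 relative to the median feature. Camera gave adjusted p of 2.1e-10, 1.08e-09, 0.00017 and 0.00041. For each of these 4 lists the adjusted p = 0.643 with an estimated correlation. Of the lists' members 1 Müller gene is held by another list. With both list scores as covariates Slc1a3 was 1.23, Clu 0.40, Gnat1 0.16, Grk1 0.33, Opn1mw 0.69 and Otx2 1.27, and none of these passed. The cone mean was then −0.0875, against −0.13 with the rod score alone. The Müller mean was 0.49 with both scores and still passed camera (adjusted p = 0.00152, range 9.61e-13 to 0.643 over all alternatives), though the adjusted p = 0.483 with an estimated correlation, and the bipolar mean was 0.23 and did not pass. Without the 5 arrays lowest in microglia or rod genes the rod mean was −0.0617, the cone mean −0.25, the bipolar mean 0.0487 and the Müller mean 0.39, and the Müller list alone of these 4 passed. It passed in 29 of 30 alternatives and the bipolar list in 25 of 30. With fry the adjusted p was 0.0432 for Müller glia, 0.0794 for rods and 0.14 for cones and bipolar cells. The exact permutation p of the list score was 0.143 for rods (score difference 1.69; 0.418 adjusted over 38 lists) and 0.0571 for Müller glia (1.39; 0.31).

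Homeostatic microglia genes averaged −0.80 at 18 months (−0.59 relative to the median feature, and −0.47 without 18-month replicate 1), with 0 of 25 passing in limma over all features or adjusted over the list alone (camera adjusted p = 0.357). The lower mean came from the 2 most alike arrays: the list score was −1.43 and −1.11 on 18-month replicates 1 and 2. On replicates 3 and 4 it was 0.50 and 0.26, against 0.355 ± 0.439 (SD, n = 4) at 3 months. For the respiratory chain list, oxidative phosphorylation, the mean was 0.12 over 30 genes (0.33 relative to the median feature; camera adjusted p = 0.00389). No member passed, 0 passed adjusted over the list alone, and the adjusted p = 0.696 with an estimated correlation. The mean was 0.19 without 3-month replicate 2, 0.07 without 3-month replicate 4, 0.06 and 0.07 without 18-month replicates 1 and 2, and 0.18 without 18-month replicate 3. It was −0.15 with the rod score as a covariate, −0.0724 with the microglia score and −0.12 with both, −0.0405 without the 3 arrays lowest in microglia genes, and −0.15 without these and 3-month replicates 3 and 4, and the list passed in none of these 5 fits. The list's members with the smallest p were Ndufb10 (0.69), Sdha (0.35), Cox4i1 (0.47) and Uqcrfs1 (−0.35; −0.14 relative to the median feature, and −0.23 without 18-month replicate 4). With both scores as covariates Ndufb10 was 0.23 and Cox4i1 0.25. No member passed among 23 disease-associated microglia, 7 MHC class II or 12 ribosomal protein genes either, nor adjusted over the list alone.

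**Figure D2:**
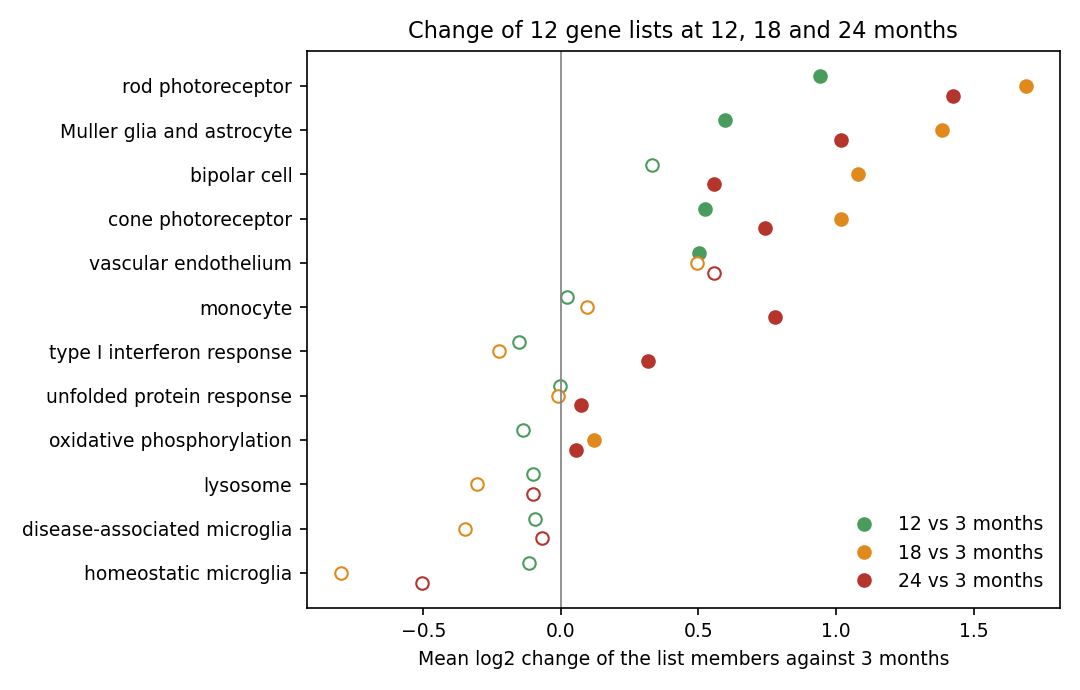
Mean log2 change against 3 months of the members of 12 gene lists at 12, 18 and 24 months, 1 point per list and comparison. Filled points passed camera at its preset correlation and open points did not; the rod list lies at 0.94, 1.69 and 1.43, and the homeostatic microglia list at −0.12, −0.80 and −0.51.

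At 18 months 1 of 35 cytokine and NF-kB genes rose, Tgfb2 (2.17), and 5 fell, among them the inhibitor gene Nfkbie (−0.75; −0.54 relative to the median feature), Traf1 (−0.40; −0.20) and Il12a (−0.49; −0.29). Of 25 Toll-like receptor signalling genes the adaptor gene Myd88 rose (1.28, SE 0.363), while Nod2 (−0.39; −0.18) and Tlr8 (−1.11; −0.90) fell. Of 26 chemokine genes Cxcr3 (−0.74; −0.54) and Ccr7 (−0.54; −0.34) fell. Of 9 MHC class I genes the peptide loading genes Tapbp (−0.78; −0.58) and Tap2 (−0.52; −0.31) fell. Of 16 complement genes Clu rose, and Hc (−0.29; −0.08) and C1ra (−0.38; −0.18) fell. Of 25 type I interferon genes Oasl2 rose (0.70, SE 0.206). Adjusted over the list alone, the counts of rises and falls were 1 and 5 for cytokines, 1 and 1 for Toll-like receptors, 0 and 0 for chemokines, 0 and 2 for MHC class I, 1 and 2 for complement, and 0 and 0 for interferon genes. None of these lists passed camera here (the interferon list, with a mean of −0.22, was 0.24 and passed with both list scores as covariates, where the adjusted p = 0.595 with an estimated correlation), and 86.8% of all 18-month calls were falls. Without 3-month replicate 4 Tlr8 was −0.73. None of these genes passed with both list scores as covariates, and Tgfb2 was then 0.48, Clu 0.40, Traf1 −0.25 and Tap2 −0.30. Myd88 was larger there at 1.84 (adjusted p = 0.0518 in limma), as was Oasl2 at 0.80. With the microglia score alone, also chosen after the data were seen, Myd88 passed (1.72, adjusted p = 0.0359 in limma).

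Among genes of uptake and metabolism, Cd36, a lipid scavenger receptor gene, rose by 1.98 (SE 0.600) and Marco fell by 0.51 (−0.31 relative to the median feature), the members of 27 phagocytosis genes that passed (0 and 0 adjusted over the list alone). Of 35 lysosome genes Gla rose (0.98), and 3 fell, among them the regulator gene Tfeb (−0.67; −0.46 relative to the median feature) and Neu1 (−0.80; −0.59); adjusted over the list alone 1 rose and 2 fell. Of 28 antioxidant genes 4 fell (1 adjusted over the list alone), among them Txn1 (−0.79; −0.58), Gpx1 (−1.01; −0.80) and Ncf4 (−1.42; −1.21). Of 27 lipid genes 1 rose, Cd36, and 2 fell, Cyp27a1 (−0.73; −0.52) and Ppard (−0.50; −0.29), the same counts adjusted over the list alone. The autophagy gene Wipi1 rose by 1.35 (SE 0.282), the sole member of 22 that passed (1 adjusted over the list alone). Of 23 genes of the unfolded protein response Sel1l rose by 1.12 (0.69 without 3-month replicate 2; 0 adjusted over the list alone). With both list scores as covariates none of these genes passed, and Sel1l was 1.76, Tfeb −0.38, Neu1 −0.53, Gpx1 −0.30 and Ncf4 −0.71.

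Of 29 proliferation genes 2 rose, among them the cyclin gene Ccna2 (1.27, SE 0.280), and 7 fell, among them Mcm7 (−0.59; −0.39 relative to the median feature) and Plk1 (−0.51; −0.30), or 2 and 11 adjusted over the list alone. Of 25 senescence and DNA damage genes 5 fell (4 adjusted over the list alone), among them Xrcc1 (−0.43; −0.22), Sirt6 (−0.50; −0.29), Bbc3 (−0.54; −0.34) and Cdkn2a, which encodes the senescence marker p16 (−0.61; −0.41). Of 29 immediate early genes 3 fell (1 adjusted over the list alone), Dusp2 (−0.60; −0.39), Klf2 (−1.10; −0.89) and Egr3 (−0.60; −0.39). Of 23 neurotrophic genes 7 fell (1 rose and 8 fell adjusted over the list alone), among them Nrtn (−0.67; −0.46) and Artn (−0.48; −0.27). Of 36 angiogenesis genes 3 rose, among them Kdr (2.24) and Tgfb2, and 4 fell, among them Tie1 (−0.49; −0.29) and Dll4 (−0.40; −0.20), or 1 and 2 adjusted over the list alone; the list's median was −0.18 and its mean 0.12. No gene named here passed with both list scores as covariates, and Klf2 was then −0.70, Egr3 −0.39, Kdr 0.75 and Tgfb2 0.48.

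Among markers of other cells in the blood or vessels, 6 of 15 neutrophil genes fell at 18 months (6 adjusted over the list alone), 5 of 15 T and NK cell genes (8), 4 of 9 B cell genes (5), 4 of 11 dendritic cell genes (5) and 2 of 4 erythrocyte genes (3), and none rose. Examples were Mpo (−0.62; −0.42 relative to the median feature), Cd8a (−0.49; −0.28), Pax5 (−0.54; −0.33), Flt3 (−0.35; −0.14) and Slc4a1 (−0.54; −0.33). The lists of these blood and immune cells were dim, with mean levels of 6.242 to 6.505 against array medians of 6.88 to 7.18. Over all 16755 features 3068 fell, 1588 of them among the dimmest (a share of 0.333). Of 15 endothelial genes 1 rose and 2 fell (1 and 2 adjusted over the list alone). Of 14 amacrine and horizontal genes 1 rose, Pax6 (2.26), and 3 fell, among them Chat (−0.45; −0.24 relative to the median feature; 1 and 4 adjusted over the list alone). Falls also passed for 1 of 13 ganglion cell genes, Pou4f1 (−0.43; −0.22; 0 adjusted over the list alone), 2 of 12 pericyte genes, among them Notch3 (−0.40; −0.20; 2), and 2 of 13 pigment epithelium genes, among them Best1 (−0.40; −0.19; 2 rose and 3 fell). No gene of 11 monocyte or 8 border-associated macrophage genes passed, nor adjusted over the list alone, and none of these lists passed camera. With both list scores as covariates none of the genes named here passed, and Pax6 was 0.51. The exact permutation p of the list score was 0.0286, the smallest possible, for erythrocytes (score difference −0.337), T and NK cells (−0.405), B cells (−0.409), pigment epithelium (0.332) and immediate early genes (−0.412), or 0.217 adjusted over 38 lists, and 0.0571 for dendritic cells (−0.37; 0.31 adjusted).

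At 24 months no gene passed the threshold, and the strongest evidence on the higher side lay with Spa17, Dld, Armcx3, Usp6nl and Cxcl13. Spa17 stood at 8.80 ± 1.12 against 5.62 ± 0.11 at 3 months (SD, n = 4; log2 change 3.18, SE 0.499, adjusted p = 0.108 in limma). Cxcl13 (feature 6932571), which encodes a B cell chemoattractant, stood at 11.04 ± 1.20 against 7.07 ± 0.34, a change of 3.97 (SE 0.808, 15.7-fold, 4.15 relative to the median feature, adjusted p = 0.108 and from 0.0313 to 0.256 over its alternatives). The changes were 1.28 for the dihydrolipoamide dehydrogenase gene Dld, 1.22 for Armcx3 and 2.28 for Usp6nl. On the lower side they were −0.60 for the sialidase gene Neu2, −0.72 for the melanocortin receptor gene Mc1r, −0.63 for Ankrd34c, −0.43 for 9530002B09Rik and −0.47 for Inpp5e, or −0.43, −0.55, −0.46, −0.26 and −0.30 relative to the median feature. In all these genes the 4 arrays at 24 months lay on 1 side of the 4 at 3 months.

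In limma 0 of 16755 features passed at 24 months, 4626 had an unadjusted p under 0.05 (626 higher, 4000 lower), the smallest adjusted p was 0.108, and 20.15% had groups without overlap, against 2.86% by chance. The 2.86% holds for each feature alone, and features that move together can raise the share. All 24-month array medians (6.92 to 6.98) lay below all 3-month medians (7.04 to 7.13), so an array-wide shift can raise it too. Without 3-month replicate 1 the count was 1 and without 3-month replicate 2 it was 2. Within the array numbers 1 to 8 (2 arrays per age) 0 passed in limma, with changes of 3.32 for Spa17 and 3.18 for Cxcl13 and a rod list mean of 0.344. Within 9 to 16 (2 per age) 5 rose, and the values were 3.03, 4.76 and 2.51.

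Genes of the type I interferon response and of monocytes averaged higher at 24 months. Of 25 interferon genes 20 had a positive change, with a mean of 0.32 (0.49 relative to the median feature), and none passed over all features (1 adjusted over the list alone). Those with the smallest p were Oasl2 (0.92, SE 0.206), Ifitm3 (0.63, 0.273), Ifit2 (0.95, 0.439) and Stat2 (0.52, 0.290). Camera gave an adjusted p of 2.16e-05 for the list, while the adjusted p = 0.762 with an estimated correlation. The list mean was 0.17 without 3-month replicate 2, 0.65 without 24-month replicate 1 and 0.04 without 24-month replicate 4. Without 3-month replicate 2 Ifit2 was 0.56 and Stat2 0.27, and without 24-month replicate 4 Ifit2 was 0.61. With both list scores as covariates Stat2 was 1.04, and none of the 4 genes passed. Of 11 monocyte genes 9 had a positive change, with a mean of 0.78 (0.95 relative to the median feature), and none passed (0 adjusted over the list alone). Among them S100a4 changed by 1.91 (SE 0.596) and S100a6 by 0.68 (0.673; 0.36, 0.32 and 1.10 without 24-month replicates 1, 2 and 3), or by 2.87 and 0.35 with both list scores as covariates, and 2 of the 11 are held by other lists. Camera gave an adjusted p of 9.03e-05, while the adjusted p = 0.253 with an estimated correlation, and the exact permutation p of its score was 0.0286, the smallest that 4 against 4 arrays can give (0.543 adjusted over 38 lists). The erythrocyte list had the same permutation p (score difference −0.285; 0.543 adjusted).

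Retinal cell lists also averaged higher at 24 months: rods by 1.43, Müller glia by 1.02, cones by 0.74 and bipolar cells by 0.56 (camera adjusted p of 1.51e-11, 4.27e-09, 0.000482 and 0.0107). For rods, Müller glia and cones the adjusted p = 0.606 with an estimated correlation, and for bipolar cells the adjusted p = 0.762 with an estimated correlation. Examples were Otx2 (2.70, SE 0.713), Grk1 (1.99, 0.662) and Slc1a3 (1.63, 0.472), and no member of the 4 lists passed (6 rod, 0 Müller, 0 cone and 1 bipolar gene adjusted over the list alone). Smaller means passed camera for oxidative phosphorylation (0.05, or 0.23 relative to the median feature, adjusted p = 0.0107) and the unfolded protein response (0.07, or 0.24, adjusted p = 0.0235). For both lists the adjusted p = 0.762 with an estimated correlation, with 0 members passing over all features or adjusted over the list alone. The count of 8 lists became 13 without 24-month replicate 1. The oxidative phosphorylation mean was −0.08 without that array, 0.13, 0.03 and 0.01 without 3-month replicates 2, 3 and 4 (not passing without replicate 4), and 0.11 without 24-month replicates 3 or 4. The unfolded protein response mean was −0.11 without 3-month replicate 2, 0.12 and 0.17 without 3-month replicates 1 and 3, and 0.16, 0.01 and 0.05 without 24-month replicates 1, 2 and 3 (not passing without 24-month replicates 2 or 3). The rod mean was 0.92 without 3-month replicate 4. The cone mean was 1.12, 0.47 and 0.49 without 3-month replicates 2, 3 and 4 and 0.48 without 24-month replicate 1. The bipolar mean was 0.88 without 3-month replicate 2, and the list no longer passed without 3-month replicates 3 (0.39) or 4 (0.40) or 24-month replicate 1 (0.32). In fits chosen after the data were seen, the oxidative phosphorylation mean was −0.17 with the rod score as a covariate, −0.0682 with the microglia score, −0.11 with both, −0.0787 without the 3 arrays lowest in microglia genes, −0.0557 without 3-month replicates 3 and 4 and −0.19 without all 5. The cone mean was −0.22 with the rod score, −0.15 with both, −0.0450 without 3-month replicates 3 and 4 and −0.31 without all 5, and the bipolar mean was −0.21, −0.0868 and −0.15 with the rod score, with both and without all 5. The rod mean was −0.12 without all 5. The Müller mean was 0.23, 0.30 and 0.26 and the unfolded protein response mean 0.34, 0.32 and 0.37 with the rod score, with both and without all 5, and both lists passed camera at its preset correlation in each. With both scores the adjusted p = 0.476 and adjusted p = 0.225 with an estimated correlation. With both scores Otx2 was 1.44, Grk1 0.59 and Slc1a3 0.90.

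Other genes with the smallest p of their lists at 24 months were Myd88 (1.49, SE 0.363), Tnf (−1.55, 0.465), Jun (−0.88, 0.259), Cfb (0.84, 0.264), Ch25h (0.87, 0.312), Cd36 (1.92, 0.600) and the homeostatic gene Fcrls (−1.07, 0.647), none of which passed. Without 24-month replicate 4 Cfb was 0.49, and Fcrls was −0.70 without 3-month replicate 3 and −0.62 without 24-month replicate 1. Ch25h with both list scores as covariates was 0.49, Jun −0.54 and Fcrls −0.58, and none of the 7 genes passed. Myd88 was 1.88 and Cd36 2.36 in that fit. With the microglia score alone, chosen after the data were seen, Myd88 passed (1.77, adjusted p = 0.0357 in limma).

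**Figure D3:**
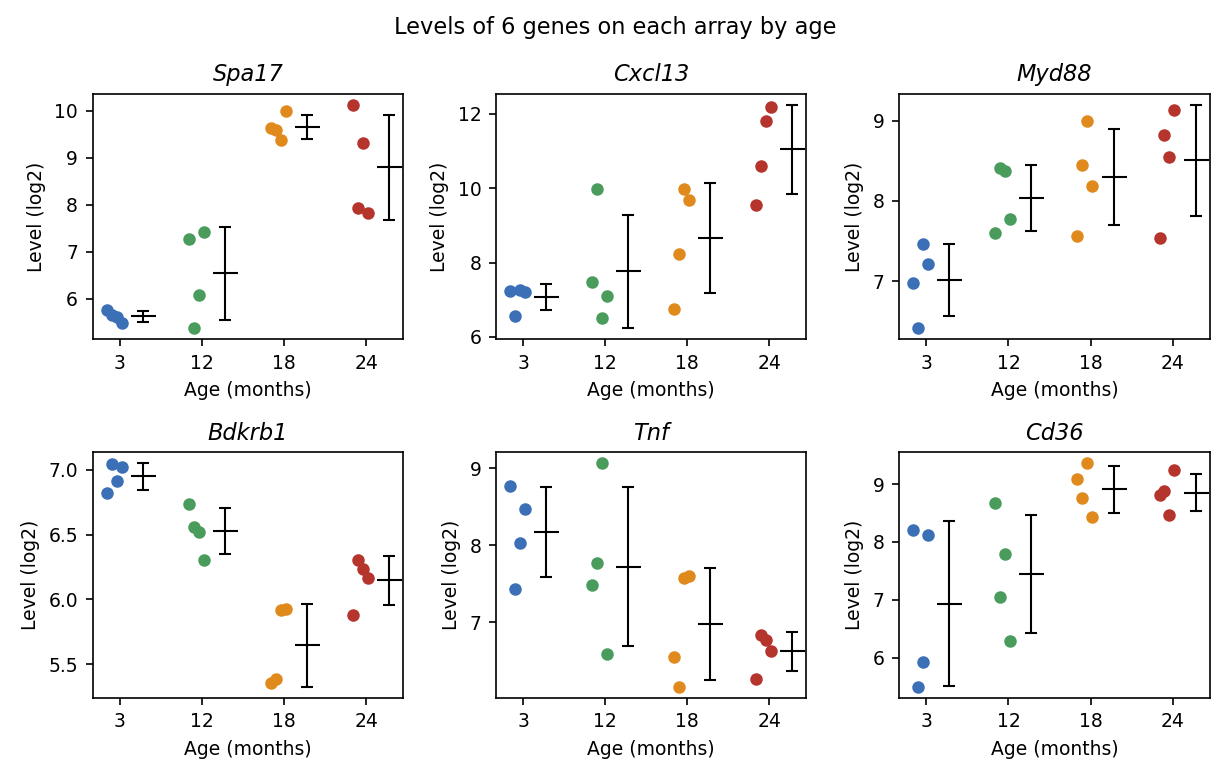
Level (log2) of 6 genes on each array by age in months, with 1 coloured point per array and the mean ± SD (n = 4) of each age in black. Spa17 lies at 5.62 at 3 months and 9.65 at 18 months, and Cxcl13 at 7.07 at 3 months and 11.04 at 24 months; the 24-month differences did not pass the threshold.

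Between later ages Tctex1d4, a dynein light chain gene, fell by 0.95 from 12 to 18 months, from 6.46 ± 0.12 to 5.52 ± 0.18 (SD, n = 4; SE 0.124, adjusted p = 0.0384 in limma). It was the sole call, among 5027 features at an unadjusted p under 0.05. The count was 0 without 3-month replicates 1, 3 or 4, 12-month replicates 1 or 3, 18-month replicates 1 or 2, or 24-month replicates 3 or 4. It was 19 without 12-month replicate 4, 3 without 24-month replicate 1, 1758 without 18-month replicate 3 and 1325 without 18-month replicate 4. From 18 to 24 months 0 features passed in limma, with 432 at an unadjusted p under 0.05 and 3 calls without 24-month replicate 1.

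Over the 4 ages Spa17 (F test adjusted p = 0.0350), Bdkrb1 (0.0350), Tctex1d4 (0.0381) and Neu2 (0.0381) differed in limma, 4 features among 16755. Bdkrb1 had means of 6.95, 6.53, 5.64 and 6.15 from 3 to 24 months and Neu2 of 7.00, 6.80, 6.33 and 6.40. The count was 0 without 3-month replicates 3 or 4, 12-month replicates 1 or 3, 18-month replicates 1 or 2 or 24-month replicate 3, and 1 without 12-month replicate 2 or 24-month replicate 2. It was 7 and 9 without 3-month replicates 1 and 2, 17 without 12-month replicate 4, 1427 without 18-month replicate 3 and 903 without 18-month replicate 4.

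A linear fit in months gave 186 features a positive and 1690 a negative slope, and 1536 of them were also called at 18 months. A slope does not show a steady change: Spa17 had means of 5.62, 6.54, 9.65 and 8.80. The smallest p-values on the positive side belonged to Dld (0.07 per month on the log2 scale, SE 0.0119), Usp6nl (0.12, 0.0213), Spa17 (0.18, 0.0335), D16Ertd472e (0.12, 0.0229) and Gla (0.06, 0.0116). On the negative side they belonged to the taste receptor gene Tas2r106 (−0.05, SE 0.00873), Neu2 (−0.03, 0.00539), Inpp5e (−0.02, 0.00379), Olfr250 (−0.06, 0.0107) and Ankrd34c (−0.03, 0.00549). All 10 had an adjusted p of 0.0439 in limma. The count of 1876 became 0 without 3-month replicates 2, 3 or 4, 12-month replicates 2 or 3, 18-month replicates 3 or 4, or 24-month replicates 1 or 2. It was 1 without 12-month replicate 4 or 24-month replicate 3, 2 without 3-month replicate 1, 975 without 18-month replicate 1 and 4123 without 24-month replicate 4. It was 0 after median centring or quantile normalization.

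The changes from 3 months were compared across features, which are not independent replicates. Their correlation was 0.631 between 12 and 18 months, 0.651 between 12 and 24 months and 0.871 between 18 and 24 months. Unchanged groups were simulated by shuffling deviations from the age means among arrays of all ages, with a shared reference drawn likewise. They gave mean correlations of 0.5, 0.459 and 0.484, and 38, 29 and 1 of 100 draws were as high. Rod scores varied more at 3 months (SD 1.56) than at 12, 18 and 24 months (0.473, 0.618 and 0.5). The simulated reference did not keep this spread of the 3-month arrays. The counts of draws therefore cannot decide whether sharing those arrays accounts for the correlations. The covariances were 0.104, 0.0839 and 0.204, against simulated means of 0.0527, 0.0490 and 0.0532. With 2 of the 3-month arrays for each comparison, the correlations averaged 0.217, 0.154 and 0.519 over 6 splits. No overlap of calls could be formed, since 12 and 24 months had 0 calls each in limma (793 and 4626 features at an unadjusted p under 0.05).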

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

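The tests of Spa17 and Cxcl13, of the array numbers, of the rises and falls after quantile normalization, and of other splits for 12 or 24 against 3 months and 24 against 18 months were chosen after the result was seen, as were the alternatives that use list scores or leave out arrays by them. The other tests here were chosen before.

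Within groups of 4 arrays, 38 of 648 gene groups and 10 of 152 list groups held an array far from the other 3, and chance gives about 1 in 20. On 24-month replicate 1 the levels were 9.91 for Cx3cr1, 9.39 for Csf1r, 10.40 for Aif1, 8.69 for P2ry12, 7.2 for Tmem119, 7.2 for Itgam, 9.10 for Ptprc, 6.26 for Naip2 and 5.6 for C1ra, each below the other 24-month arrays. Its list scores were −1.77 for homeostatic microglia, −0.78 for disease-associated microglia, −0.85 for Toll-like receptors, −0.69 for lysosome, −0.52 for cytokines and −0.44 for MHC class I, below the others, and 1.37 for pigment epithelium, above them. On 3-month replicate 2 Ly6m stood at 9.80, Ch25h at 6.67 and Otx2 at 9.62, above the other 3-month arrays. Below them were Cxcl13 at 6.56, Mrc1 at 8.78, Ptprc at 10.28, Cx3cr1 at 12.04, Aif1 at 11.61 and the phagocytosis score at −0.32. On 12-month replicate 4 Stk39 stood at 10.1, Etnppl at 8.93 and Slc1a3 at 9.90, above the others, and Csf1r at 11.0 and the complement score at −0.26, below them.

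On 18-month replicate 4 Cx3cl1 stood at 6.76, above the other 18-month arrays, and Sel1l at 9.22, Ero1a at 7.81 and Rbpms at 7.80, below them. On 18-month replicate 3 Stk39 stood at 9.13, below the others, and Ifitm3 at 11.27, above them. On 3-month replicate 4 Armcx3 stood at 8.70, below the others, and Rars2 at 8.52 and H2-Oa at 8.21, above them. The remaining such levels were Atp6v0d2 at 5.67 and Map1lc3b at 10.81 on 12-month replicate 2, Ankrd34c at 5.89 on 12-month replicate 1, Ttr at 8.93 on 3-month replicate 3, Hc at 5.32 and Dusp2 at 6.94 on 24-month replicate 4, all above their groups. Below their groups were Best1 at 7.2 on 3-month replicate 1, and Sdha at 10.63 and the antioxidant score at −0.04 on 24-month replicate 3. Tctex1d4 differed between the changes at 18 and 12 months by −0.95, a tested difference.

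A different mixture of microglial and retinal RNA may account for part of the 3534 calls at 18 months: the slope of each feature on the rod minus homeostatic microglia score, taken within the 12- and 24-month arrays, gave the right sign for 88.1% of 3530 called features, against 76.0% of all, although its predicted medians (0.605 for rises, −0.116 for falls) were below the observed 1.29 and −0.464 in size. Quantile normalization left 38 calls, 14 of the 466 rises and 24 of the falls. The median change of the rises went from 1.29 (median SE 0.357) to 1.24 (0.354) and that of the falls from −0.464 (0.127) to −0.273 (0.103). A shift of dim features between arrays thus does not account for the size of the rises and stays open for the falls. Most rises no longer passed, so their being called did depend on the scaling. With the 2 groups of array numbers as a block the count was 3622, which argues only against an offset between these 2 groups as the whole cause. This fit gives more weight to 3-month replicates 3 and 4, lowest in rod genes (−2.11 and −2.53), so number and rod content were not separated there. These 2 arrays had numbers 15 and 16, and 18-month replicates 1 to 4 had 9, 10, 12 and 14. Within the numbers 9 to 16 order and age were thus not separated, and the block cannot decide on the order. Only the real split gave as many calls (1 of 35, the smallest share possible, highest other 566). This argues against chance, for this test alone, if 18-month replicates 1 and 2 (rank correlation 0.990) count as independent. Averaged, these replicates left 3 calls, and 3 and 1 were left without replicate 1 or 2. Age stays open as an untested explanation beside mixture and scaling.

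Spa17 rose by 4.03 (SE 0.499) at 18 months. The same mixture slope within 3 and 12 months predicted 0.45, which argues against mixture as the whole cause, though Spa17 lay near the lower end of the scale at 3 months (5.49 to 5.75) and the slope there says little. Arrays of like composition differed as well: 18-month replicate 3 (rod score −0.17, microglia score 0.50) stood at 9.38 and 3-month replicate 1 (−0.14 and 0.43) at 5.75. With both scores as covariates the change was 3.66 (SE 0.570), and the call ended (adjusted p = 0.0518, range 5.01e-05 to 0.304): the change was smaller against its error, and 3 calls were left over all features, on which the adjustment also depends. Age, and any difference in the source of the animals that the labels do not give, stay open and untested.

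Cxcl13 was 3.97 (SE 0.808) higher at 24 months without passing. The mixture slope within 12 and 18 months predicted a change of −1.70 (SE 0.570), opposite to the observed one, so mixture is unlikely as its cause. With both scores as covariates the change was 4.48 (SE 0.698, adjusted p = 0.0668, range 0.0313 to 0.256). Age and incoming cells that carry the transcript stay open, and neither was tested.

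For the other comparisons, splits of the arrays bear on chance as follows. At 12 and at 24 months limma made 0 calls, so all splits (35 of 35) were as large by construction and say nothing about chance (highest other 1 each; 793 and 4626 features at an unadjusted p under 0.05). The same holds for 24 against 18 months (0 calls in limma, 35 of 35, highest other 687; 432 features at an unadjusted p under 0.05). The split with 687 calls set 24-month replicate 1 and 18-month replicates 1, 2 and 4 against the rest and had a microglia score difference of −1.43, which points to a structure of the samples. Chance could not be excluded for 18 against 12 months (1 call, 4 of 35, highest other 34). Regroupings with as many calls were few for the 4 ages (4 calls, 3 of 100 regroupings, highest other 4286) and for the trend (1876 calls, 2 of 100, highest other 2853). This argues against chance only if 18-month replicates 1 and 2 count as independent, and for each test alone, with no adjustment over the tests. Averaging these 2 arrays left 0 calls for the 4 ages in limma (5272 features at an unadjusted p under 0.05 as first fitted) and 1506 for the trend, and regroupings with far more calls point again to a structure of the samples. The count for the 4 ages was 0 without 3-month replicates 3 or 4, 12-month replicates 1 or 3, 18-month replicates 1 or 2 or 24-month replicate 3, and up to 1427 without 18-month replicate 3. The count for the trend was 0 without 3-month replicates 2, 3 or 4, 12-month replicates 2 or 3, 18-month replicates 3 or 4 or 24-month replicates 1 or 2, and up to 4123 without 24-month replicate 4.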

How the results depend on the processing

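The alternatives with list scores as covariates, without arrays low in microglia or rod genes, and with 18-month replicates 1 and 2 averaged were chosen after the result was seen; the others were chosen before. Of the alternative values of named genes 4422 kept their direction and side of the threshold, 1619 lost a call, 92 gained one and 26 reversed; of the lists 465 kept it, 74 lost a call, 1 gained one and 42 reversed. The values that kept it include those of genes and lists with no call to lose. All losses fall on the 92 gene results and 17 list results called in the main fit. Except where fewer features, arrays or ages were tested, the cause was not tested. The number of arrays and the compressed low end of the signal limit precision.

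Counts of calls are given for 12, 18 and 24 against 3 months, 18 against 12, 24 against 18, the 4 ages (F) and the trend, and counts of lists per comparison, where they moved by over 1.5 times. Counts of 0 are from limma, with 793, 6979, 4626, 5027, 432, 5272 and 6410 features at an unadjusted p under 0.05 in these 7 tests as first fitted. Without the dimmest features the counts were 12 at 18 months, 0 for 18 against 12, 1 for F, 0 for the trend, 2 lists at 12 months and 5 lists at 24. Quantile normalization gave 38, 0 for 18 against 12, 2 for F and 0 for the trend; median centring gave 100, 2, 2 and 0. All of the 12, 38 and 100 calls were among the 3534. A trended and robust variance gave 9 for F and 2968 for the trend. Array weights gave 10664 at 18 months, 2087 at 24, 9405 for 18 against 12, 4776 for 24 against 18, 10501 for F and 0 for the trend, with the largest weights on 18-month replicates 1 (4.55) and 2 (3.13), the 2 most alike arrays. Fitting only the 2 ages compared gave 3 at 18 months and 0 for 18 against 12.

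The replicate number as a block gave 518 at 18 months and 0 for 18 against 12, F and the trend. The numbers do not pair the samples: correlations of 24 same-number pairs ran from −0.343 to 0.73, with 11 over 0.1, and 7 of 16 arrays were closest to their own number. The array numbers in groups (1 to 8 or 9 to 16) as a block gave 5 for 18 against 12 and 0 for F and the trend, with similarities across features of 0.0481 (12 and 18 months) and 0.335 (12 and 24), and list means at 12 months of 0.30 for homeostatic microglia and −0.0601 for cones. The array number as a covariate gave 1 at 12 months and 0 for 18 against 12 and the trend. An adjusted p of 0.1 gave 6298 at 18 months, 2434 for 18 against 12, 2968 for F and 5399 for the trend. An unadjusted p of 0.05 with 1.5-fold gave 309, 2047 and 869 at 12, 18 and 24 months, 976 for 18 against 12, 162 for 24 against 18 and 1380 for F. Age on a log2 scale gave 590 for the trend. With an estimated correlation 0, 0 and 0 lists passed at 12, 18 and 24 months, and with fry 0, 10 and 1. Of the 17 lists that camera called fry lost 16, all but Müller glia at 18 months (adjusted p = 0.0432). The other 9 at 18 months were lower: senescence, neutrophil, erythrocyte and T and NK cell genes (0.0173 each), neurotrophic, immediate early and B cell genes (0.0216 each), and cytokine and dendritic cell genes (0.046 each). The median feature itself differed by −0.21 there. Senescence genes averaged −0.02 and neurotrophic genes −0.05, or 0.19 and 0.15 relative to the median feature. The other lists named were at −0.25 to −0.13 relative to it. The 1 at 24 months was the erythrocyte list, lower (0.0439). The lost lists had 0.982 at 12 months. At 18 months they had 0.0794 (rods), 0.14 (cones, bipolar cells) and 0.497 (oxidative phosphorylation). At 24 months they had 0.117 (monocytes), 0.21 (rods, Müller glia), 0.425 (cones), 0.744 (interferon), 0.765 (bipolar cells) and 0.842 (oxidative phosphorylation, unfolded protein response). Fry asks whether a list moved on balance and camera whether it moved against the other genes. Splitting the 3-month arrays gave similarities of 0.217, 0.154 and 0.519.

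With the rod score the counts were 0 at 18 months, for 18 against 12, F and the trend, with 7, 8 and 14 lists. Ulk2 at 18 months was then 0.00928, H2-Oa at 24 months 0.0435, cones −0.11, −0.13 and −0.22 at 12, 18 and 24 months, endothelium −0.0133 at 12, oxidative phosphorylation −0.15 and −0.17 at 18 and 24, and bipolar cells −0.21 at 24. At 18 months Itgam was 0.48, Ptprc 0.19, Aif1 0.0435 and P2ry12 0.11. With the microglia score they were 29 at 18 months, all among the 3534, 2 at 24 (Cxcl13 at 4.555 and Myd88 at 1.768, adjusted p = 0.0357 each in limma), 0 for 18 against 12, 1 for F and 2 for the trend, with oxidative phosphorylation at −0.0724 and −0.0682, and at 18 months Itgam at 0.0781, Cx3cr1 at 0.0019 and P2ry12 at 0.10. With both scores they were 3 at 18 months, 1 at 24, 0 for 18 against 12, F and the trend, and 2 lists at 12 months, with cones at −0.0053, −0.0875 and −0.15, oxidative phosphorylation at −0.12 and −0.11, bipolar cells at −0.0868 at 24 months, and Itgam at 0.30 and Ptprc at 0.0242 at 18 months. Without the 3 arrays lowest in microglia genes they were 0 at 18 months, for 18 against 12, F and the trend, 1 for 24 against 18, and 13 lists at 24 months; at 18 months Oasl1 was 0.0396, Itgam 0.0476, Cx3cr1 0.0364, Aif1 0.0033, P2ry12 0.0232 and Tmem119 0.0160. Then homeostatic microglia were at 0.0281 and 0.0317 and oxidative phosphorylation at −0.0405 and −0.0787 at 18 and 24 months.

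Without the 2 arrays lowest in rod genes the counts were 10 at 18 months, 5 at 24, and 0 for 18 against 12, F and the trend. At 12 months homeostatic microglia were then 0.17, rods −0.36 and cones −0.26, and at 24 months oxidative phosphorylation was −0.0557 and cones −0.0450. Without these 5 arrays the counts were 0 at 18 months, for 18 against 12, F and the trend, with 14 lists at 18 months and 13 at 24. At 18 months Oasl1 was then 0.067, Ifi35 0.14, Itgam 0.65, Ptprc 0.38, Cx3cr1 0.20, Csf1r 0.12, Aif1 0.25, P2ry12 0.19 and Tmem119 0.33. At 12 months homeostatic microglia were 0.17, rods −0.36 and cones −0.26. At 18 and 24 months homeostatic microglia were 0.31 and 0.32, oxidative phosphorylation −0.15 and −0.19, rods −0.0617 and −0.12, and cones −0.25 and −0.31, with bipolar cells at −0.15 at 24 months. Averaging 18-month replicates 1 and 2 gave 3 at 18 months, and 0 for 18 against 12 and F.

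Leaving out each array in turn gave 0 to 0 at 12 months, 0 to 5115 at 18 (0, 10, 3, 1 and 1253 without 3-month replicates 4 and 3, 18-month replicates 1 and 2 and 3-month replicate 2), 0 to 2 at 24 (1 and 2 without 3-month replicates 1 and 2), 0 to 1758 for 18 against 12, 0 to 3 for 24 against 18 (3 without 24-month replicate 1), 0 to 1427 for F, 0 to 4123 for the trend, and 2 to 7, 5 to 6 and 6 to 13 lists. Similarities ran from 0.386 to 0.744, 0.450 to 0.753 and 0.701 to 0.906, the 0.701 without 24-month replicate 1. The homeostatic microglia mean ran from −0.33 without 3-month replicate 2 to 0.11 without 12-month replicate 4 at 12 months, from −1.12 without 18-month replicate 3 to −0.47 without 18-month replicate 1 at 18 months, and from −0.72 without 3-month replicate 2 to 0.0317 without 24-month replicate 1 at 24 months. At 24 months the unfolded protein response mean ran from −0.11 without 3-month replicate 2 to 0.17 without 3-month replicate 3, and oxidative phosphorylation from −0.0787 without 24-month replicate 1 to 0.13 without 3-month replicate 2.

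Over all alternatives the adjusted p of the lists ran at 12 months from 6.11e-17 to 0.982 for rods, 9.95e-09 to 0.982 for Müller glia, 0.000404 to 0.995 for cones and 2.08e-05 to 0.982 for endothelium. At 18 months it ran from 4.9e-17 to 0.643 for rods, 9.61e-13 to 0.643 for Müller glia, 1.16e-06 to 0.643 for bipolar cells, 1.97e-06 to 0.952 for cones and 0.000389 to 0.816 for oxidative phosphorylation. At 24 months it ran from 7.61e-21 to 0.606 for rods, 6e-13 to 0.606 for Müller glia, 3.08e-06 to 0.989 for cones, 5.57e-05 to 0.966 for bipolar cells, 1.14e-13 to 0.762 for interferon genes, 1.34e-05 to 0.253 for monocytes, 0.00182 to 0.945 for oxidative phosphorylation and 1.65e-06 to 0.842 for the unfolded protein response.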

Other observations

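The fits in this part, with both list scores as covariates or without the 3 arrays lowest in microglia genes, were chosen after the result was seen. With both scores as covariates, lists passed camera in each comparison with 3 months. At 12 months antioxidant genes averaged 0.27 (camera adjusted p = 0.0164; adjusted p = 0.318 with an estimated correlation) and immediate early genes 0.20 (0.0164; adjusted p = 0.959 with an estimated correlation). At 18 months interferon genes averaged 0.24 (0.00252), against −0.22 without the covariates, and T and NK cell genes −0.51 (0.0292). For these 2 lists the adjusted p = 0.595 with an estimated correlation. Unfolded protein response genes averaged 0.30 (0.00152), lysosome genes 0.12 (0.0496) and Müller glia genes 0.49 (0.00152) at 18 months. For these 3 lists the adjusted p = 0.483 with an estimated correlation. At 24 months interferon genes averaged 0.63 (camera adjusted p = 2.56e-10), monocyte genes 0.98 (0.000125), lysosome genes 0.19 (0.000305), Toll-like receptor genes 0.29 (0.00464), antioxidant genes 0.27 (0.00464) and phagocytosis genes 0.21 (0.0104). For these 6 lists the adjusted p = 0.12 with an estimated correlation. Disease-associated microglia genes averaged 0.27 (0.00434) and unfolded protein response genes 0.32 (6.55e-05). For these the adjusted p = 0.225 with an estimated correlation. Of the 23 disease-associated genes 11 are held by other lists. Chemokine genes averaged 0.34 (0.0281; adjusted p = 0.473 with an estimated correlation) and Müller glia genes 0.30 (0.00464; adjusted p = 0.476 with an estimated correlation). Without covariates the 24-month means were −0.10 for lysosome, −0.11 for Toll-like receptor, −0.08 for phagocytosis and −0.07 for disease-associated genes. Relative to the median feature they were 0.07, 0.06, 0.10 and 0.10. The other lists named at 24 months had positive means. At 18 months lysosome and unfolded protein response genes were at −0.31 and −0.01. The homeostatic score is a covariate, so higher means of microglial lists are no independent evidence in this fit.

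Without the 3 arrays lowest in microglia genes 7 lists passed at 18 months: interferon genes (0.0855, camera adjusted p = 0.018), Toll-like receptor genes (0.11, 0.0480), monocyte genes (0.35, 0.0233), rods (1.24, 7.89e-09), Müller glia (0.97, 2.49e-08), cones (0.53, 0.00311) and bipolar cells (0.52, 0.0149). For these 7 lists the adjusted p = 0.747 with an estimated correlation. In this fit 13 lists passed at 24 months. The 3 arrays were left out for their low homeostatic microglia scores, and all are of 18 or 24 months. Leaving them out moved the homeostatic list mean at 24 months from −0.51 to 0.0317. Higher means of microglial gene lists at 18 or 24 months are therefore no independent evidence in this fit. Interferon genes averaged 0.65 (2.15e-12) and monocyte genes 0.77 (5.01e-05); for these lists the adjusted p = 0.348 and adjusted p = 0.311 with an estimated correlation. Disease-associated microglia genes averaged 0.21 (0.00056), complement genes 0.24 (0.0362), chemokine genes 0.40 (0.00274), phagocytosis genes 0.18 (0.0046), unfolded protein response genes 0.16 (0.000599), rod genes 1.19 (1.82e-08), Müller glia genes 0.84 (1.49e-07) and cone genes 0.48 (0.00277). For these 8 lists the adjusted p = 0.495 with an estimated correlation. Lysosome genes averaged 0.14 (0.000307; adjusted p = 0.561 with an estimated correlation), Toll-like receptor genes 0.18 (0.0075; adjusted p = 0.589 with an estimated correlation) and homeostatic microglia genes 0.0317 (0.0198; adjusted p = 0.705 with an estimated correlation). Antioxidant genes averaged 0.0976 and did not pass (0.0695).

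With both scores as covariates 3 genes passed at 18 months in limma: Bdkrb1 (−1.18, SE 0.133, adjusted p = 0.0168), the co-chaperone gene Bag2 (−0.77, SE 0.107, 0.0490) and Dld (1.58, adjusted p = 0.0490). At 24 months Bag2 passed (−0.85, adjusted p = 0.0321). Without the covariates the changes at 18 months were −1.31 for Bdkrb1, −0.48 for Bag2 and 1.40 for Dld, and at 24 months −0.59 for Bag2.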
